A study of Mus musculus with 24 samples.

How the data were processed

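RNA was measured by sequencing in 24 libraries of mouse CD4 T cells, in 2 cohorts with 4 groups of 3 libraries each. According to the labels, total RNA was prepared with a stranded kit that removes ribosomal and globin RNA and read from a single end over 75 bp. Cells were grown with 15% serum and 2 mM glutamine, and activation through CD3 and CD28 lasted 24 h. The labels give no schedule for the induction of CreERT2.

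The authors deposited a single table of 46981 mouse gene identifiers by 24 libraries, in RPM, reads scaled to a total of 1000000 per library. The submitters' processing notes name the builds GRCm38 and mm10. The aligner, the counter and the annotation are not given in the sources used here. Each column summed to that total. Every value above 0 came out as a whole count, within a tolerance of 0.01, once a correction for collisions among 4096 identifiers of 6 bases was inverted and the scaling undone. The highest possible count per gene and library is then 4095. The labelled protocol names no molecular identifiers, so the type of library, and with it the part of each transcript that was read, is left open. Recovered counts ranged from 388902 to 1087675 per library, 1 count was worth 0.677 to 2.28 RPM, and the floor that a count of 0 allows (3 counts) lay at 2.03 to 6.83 RPM per library. Such floors cover counting error only.

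Gene symbols, biotypes and positions came from GENCODE mouse release M21 on GRCm38, which matched 46206 identifiers; the other 775 were kept without a symbol. A further 68 identifiers repeated the symbol of another and were kept as separate genes. Per library, the summed RPM of 1685 olfactory and vomeronasal receptor genes served as a measure of background, because T cells are not known to express these families.

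Differences were tested with limma 3.58.1 in R 4.3.3 (linear models with a mean-variance trend and robust empirical Bayes) on log2(RPM + 0.5). The pseudocount pulls fold changes of genes near the floor toward 0, so their folds are understated. Genes with at least 1 RPM in at least 3 libraries of a fit were kept. Each cohort was fitted by itself, with its 12 libraries in 4 groups sharing an estimate of the spread. The contrasts were knockout (KO) against wild type (WT) at rest and after activation, activated against resting for each genotype, and the interaction of genotype and activation. All 24 libraries entered a single fit for the Acly effect minus the Pdha1 effect in activated cells. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with 0.05 as the threshold and no minimum fold. The labels do not say whether replicates are separate animals, so p-values measure the spread between these samples. Values after ± are standard errors of the fitted log2 change or, where said, standard deviations (SD) over 3 libraries.

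Gene lists (35 lists, 722 symbols, 717 of them in the table), the tests, their alternatives and the rule for naming genes were fixed before the data were examined. Lists with at least 3 tested members were tested with camera, which compares a list with all other genes, at a preset correlation between genes of 0.01, and adjusted over the lists of a contrast. Beside it stand camera with an estimated correlation and fry, which tests whether the genes of a list move, on balance, in a single direction and compares them with no other genes. The rule names Acly and Pdha1 in every sample, the 10 largest rises and falls of each contrast of genotypes and the 5 largest of each activation contrast among genes past the threshold with at least 3 RPM in the higher group and the same direction in all 9 pairs of libraries, without predicted models and receptor segments, and up to 4 members with the smallest p per list and contrast. Other genes are said to have been chosen after their values were seen. A fold against a group with no count in any library is given as a bound against the floor of 3 counts per library.

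Alternatives fixed in advance were pseudocounts of 0.1 and 1, no filter and a filter of 5 RPM, scaling in the manner of TMM, quantile normalization, a fit of only the groups compared, terms for replicate numbers, limma without trend and robust, an estimated correlation for the lists, and leaving out each library in turn. Alternatives added after seeing the data were edgeR 4.0.16 and DESeq2 1.42.0 on the recovered counts after the collision correction, rounded to whole numbers, a background covariate, an Xist covariate, and fits without the 2 or 3 Pdha1 libraries that stood apart. The 2 were KO resting 3 and WT activated 3, and the third was WT activated 1, which leaves WT activated 2 alone in its group. No library was left out of the comparisons as reported. The power of limma and edgeR in each contrast, and of camera for the cholesterol list in activated KO against WT cells of each cohort, was checked on simulated data drawn from the real means, depths and dispersions, with known folds in 200 genes or a shifted list. Each fold was given to 50 genes in a single draw, so the percentages are coarse. Changed genes were taken from all genes with a mean of at least 1 count, so the percentages do not hold for well expressed genes alone. Genes were drawn independently of each other. Tables and plots were made with python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.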

Results

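RNA was sequenced from CD4 T cells of mice labelled as knockouts of either of 2 enzymes of acetyl-CoA supply, and from their WT controls. Acly encodes ATP citrate lyase, which makes acetyl-CoA from citrate outside the mitochondria, and its deletion was to come from Cre under the Cd4 promoter. Pdha1 encodes the E1 alpha subunit of pyruvate dehydrogenase, which makes acetyl-CoA from pyruvate inside them, and its deletion was to come from CreERT2, a Cre that tamoxifen switches on. Each deletion had its own WT group, and cells were taken at rest or 24 h after activation through CD3 and CD28, which gives 8 groups of 3 libraries. In the Acly cohort, libraries 1 to 3 held 664824, 517689 and 544738 recovered counts in resting WT, 668894, 662021 and 642029 in resting KO, 880865, 1087675 and 965724 in activated WT, and 1081628, 899677 and 806545 in activated KO. In the Pdha1 cohort they held 1023990, 654524 and 967436 in resting WT, 975222, 484287 and 881235 in resting KO, 388902, 860862 and 682674 in activated WT, and 1023705, 883255 and 978143 in activated KO.

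Resting libraries held a larger share of background than activated ones. Olfactory and vomeronasal receptor genes, which T cells are not known to use, took 95330 to 109575 RPM in the resting and 30101 to 40962 RPM in the activated libraries of the Acly cohort. Protein-coding genes outside these families took 49.2% to 55.1% and 70.9% to 74.8%. In the Pdha1 cohort the receptor genes took 103462 to 108363 RPM in 5 resting libraries and 66286 RPM in the library labelled KO resting 3. In its activated libraries they took 26381, 72243 and 105375 RPM in WT 1 to 3 and 75403, 82360 and 89326 RPM in KO. Xist, the RNA that silences an X chromosome in female cells, and the Y-linked Ddx3y differed within groups of the Acly cohort: in activated KO libraries 1 to 3, Xist stood at 6.80, 55.9 and 132 RPM and Ddx3y at 78.0, 1.76 and 4.28 RPM. In all 12 Pdha1 libraries Ddx3y was present, at 37.6 to 124 RPM. T cell receptor alpha segments (71 genes summed per library) had group means of 7.04 to 13.9 RPM, beta segments (22 genes) 1.66 to 7.03 RPM, immunoglobulin heavy chain segments (83 genes) 6.68 to 21.8 RPM and kappa segments (101 genes) 4.47 to 24.4 RPM.

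The Acly transcript (ENSMUSG00000020917, GRCm38 chromosome 11, 100476353 to 100528000) was lower in activated KO cells in every library. It stood at 104, 111 and 109 RPM in WT libraries 1 to 3 (mean 108 ± 3.52, SD, n = 3) and at 11.3, 10.6 and 15.0 RPM in KO (12.3 ± 2.35). At rest it stood at 5.80, 9.87 and 8.94 RPM in WT and at 8.0, 1.06 and 5.04 RPM in KO, near the floor of 3 counts, where a loss was not detectable at this depth (log2 change −1.02 ± 0.44, limma, adjusted p = 0.739). Across the Pdha1 cohort, Acly stood at 5.42, 1.04 and 11.3 RPM in resting WT, 8.80, 1.69 and 33.7 RPM in resting KO, 68.6, 32.0 and 4.28 RPM in activated WT and 31.2, 24.9 and 19.2 RPM in activated KO.

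The Pdha1 transcript (ENSMUSG00000031299, GRCm38 chromosome X, 160122209 to 160138413) did not separate the genotypes of its cohort as labelled. It stood at 6.78, 3.14 and 6.01 RPM in resting WT and at 7.33, 0 and 25.9 RPM in resting KO. After activation it stood at 84.7, 40.8 and 5.35 RPM in WT (43.6 ± 39.7, SD, n = 3) and at 30.4, 27.4 and 20 RPM in KO (25.9 ± 5.36). The overlap came from WT activated 3, which resembled resting libraries, as described below. Without it every KO value lay below both WT values. Acly, which is not the target in this cohort, stood in the same order, and the background share also differed between the genotypes in that set. With all libraries as labelled, the limma log2 change of KO against WT was −0.07 in activated and −0.25 in resting cells, and its sign turned in 4 and 3 of 28 alternative settings. Where in a transcript the reads fell is unknown, and reads outside the deleted exons check nothing, so the table neither shows nor excludes the deletion. The labels give the KO mice as Pdha1 fl/fl, which names 2 floxed copies of an X-linked gene, while the Y-linked Ddx3y was present in every library of the cohort and male cells hold a single X. The genotype behind the label is therefore open, and so is what each Pdha1 KO value measures. In the Acly cohort Pdha1 stood at 18.6, 16.9 and 8.94 RPM in resting WT, 9.14, 10.7 and 7.57 RPM in resting KO, 97.8, 112 and 97.2 RPM in activated WT and 94.3, 97.4 and 101 RPM in activated KO.

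**Figure D1:**
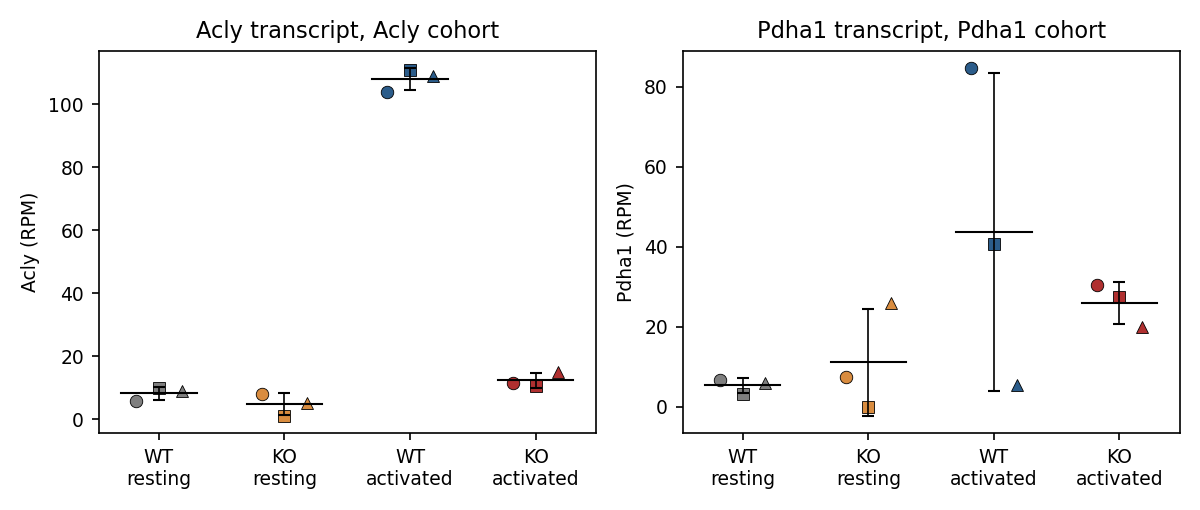
Acly in the Acly cohort (left) and Pdha1 in the Pdha1 cohort (right) in RPM (vertical axes) by group; points are libraries, lines are group means and bars are SD. Acly stood at 104 to 111 RPM in activated WT and at 10.6 to 15.0 RPM in activated KO cells, while Pdha1 overlapped between the genotypes as labelled.

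The main question of the series is what activated T cells express without ATP citrate lyase. Activated Acly KO cells held more transcripts of cholesterol synthesis than WT cells, and fewer of the G2 and M phases of the cell cycle, of replication-dependent histones and of glycolysis. With an estimated correlation cholesterol synthesis kept its call, and the other 3 did not (adjusted p = 0.124, 0.0700 and 0.134). The histone genes also lay, on average, near the floor of 3 counts. Single genes past the threshold were few. Acly fell by 3.10 ± 0.44 on the log2 scale (adjusted p = 0.000429). Thy1 (ENSMUSG00000032011, chromosome 9, 44043384 to 44048579), the T cell surface glycoprotein CD90, fell by 1.28 ± 0.23 (limma, adjusted p = 0.0332), from 406 ± 71.0 to 166 ± 12.1 RPM (SD, n = 3). Both were lower in all 9 pairs of a KO and a WT library. Over 31311 genes tested these 2 were all that limma called, with 1087 genes (418 higher, 669 lower) at an unadjusted p under 0.05 where 1566 would be expected by chance. The count depended on the fit: limma called 39 genes (4 higher, 35 lower) when only the groups compared were fitted, and 8 (3 higher, 5 lower) with no filter. edgeR called 16 genes, 8 in each direction, and DESeq2 called 4 (Acly, Thy1, Hmgcs1 and Bri3bp). Genes that only these tools or fits without libraries called are named here and below after their values were seen. By edgeR, Hmgcs1 and Klf2 were higher in KO cells, by 1.63 and 1.84 (adjusted p = 4.15e-07 and 0.000759), and Thy1 was lower (adjusted p = 0.00623).

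The cholesterol synthesis list was higher in activated Acly KO cells (24 genes, 22 with a positive log2 change, median 0.64, camera adjusted p = 3.66e-10, and 0.041 with an estimated correlation). None of its genes passed the threshold over all genes and 1 rose adjusted over the list alone. That gene was Hmgcs1 (ENSMUSG00000093930, chromosome 13, 119690379 to 119708260), which makes the HMG-CoA that the pathway starts from, at 60.0 ± 14.1 RPM in WT and 174 ± 47.0 RPM in KO (log2 change 1.53 ± 0.34, list-adjusted p = 0.00172). The later enzymes Lss (0.99 ± 0.34), Cyp51 (0.85 ± 0.34) and Msmo1 (0.65 ± 0.28) did not pass. The mean log2 value of the list was 5.52 to 5.77 in the 3 KO libraries and 4.98 to 5.15 in the WT libraries. The fatty acid synthesis list had a median of 0.00 (camera adjusted p = 0.825). In the acetyl-CoA supply list, Acly was the only call, adjusted over all genes or over the list alone (median −0.14, camera adjusted p = 0.0610).

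Genes of the G2 and M phases were lower (28 genes, 3 positive, median −0.56, camera adjusted p = 2.67e-07), a call that was lost with an estimated correlation (adjusted p = 0.124 with an estimated correlation). Adjusted over the list alone 1 gene fell, Ube2c (ENSMUSG00000001403, chromosome 2, 164769898 to 164778822), which carries ubiquitin to mitotic cyclins, by 1.73 ± 0.49 (list-adjusted p = 0.0269). The mitotic cyclin Ccnb1 (−1.14 ± 0.40) and the kinase Plk1 (−1.82 ± 0.75) did not pass. Replication-dependent histones were lower too (36 genes, 8 positive, median −0.82, camera adjusted p = 1.26e-05, adjusted p = 0.0700 with an estimated correlation, fry adjusted p = 0.0365), with Hist1h3h at −2.31 ± 0.79 and no gene passing alone. The mean log2 value of the histone list was 1.99 to 2.35 in the WT and 1.498 to 1.62 in the KO libraries. On average its genes thus lay near the floor of 3 counts, though some members lay well above it. Whether the type of library, left open above, bears on this list was not tested. Genes of the S phase had a median of −0.13 (camera adjusted p = 0.333). All 19 glycolysis genes had negative changes (median −0.34, camera adjusted p = 8.18e-05, adjusted p = 0.134 with an estimated correlation), among them the enzymes Eno1 (−0.72 ± 0.23) and Hk2 (−0.95 ± 0.39) and the lactate carrier Slc16a3 (−1.72 ± 0.73), of which none passed. The 3 KO libraries lay below every WT library in the mean of each of these 3 lists, and also of the S phase, TCA cycle, one-carbon, acetyl-CoA supply, glutamine, unfolded protein response, ribosome biogenesis and T cell identity lists.

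Naive and quiescence genes were higher by camera (23 genes, 13 positive, median 0.20, adjusted p = 0.0213, and adjusted p = 0.366 with an estimated correlation). Among its genes that rose adjusted over the list alone were Klf2, a transcription factor of resting T cells (ENSMUSG00000055148, chromosome 8, 72319033 to 72321656, 7.67 ± 3.67 RPM in WT and 26.5 ± 4.05 RPM in KO) and the growth inhibitors Tob1 (1.84 ± 0.56) and Btg1 (0.78 ± 0.27). T cell identity genes were lower (15 genes, 2 positive, median −0.36, camera adjusted p = 0.00568, and 0.498 with an estimated correlation), with Cd4 at −0.55 ± 0.25. Smaller shifts of the same kind were called in glutamine and anaplerosis (median −0.23, adjusted p = 0.0213), the unfolded protein response (median −0.30, adjusted p = 0.0213) and ribosome biogenesis (median −0.26, adjusted p = 0.0230), all camera adjusted and at 0.126, 0.126 and 0.322 with an estimated correlation. Got1 (−0.88 ± 0.30) and Hyou1 (−0.39 ± 0.27) did not pass, and the ribosome assembly factor Wdr12 fell by 0.86 ± 0.25 adjusted over the list alone (adjusted p = 0.0378). Isg15, an interferon-induced gene, rose by 1.53 ± 0.42 adjusted over its list alone (adjusted p = 0.0254), while the interferon list had a median of 0.02 (camera adjusted p = 0.0849). T cell activation genes (median −0.22, adjusted p = 0.223) and cytokines (adjusted p = 0.825, where the test pointed up and the median was −0.06) were not called. The sign of the test and of the median also parted in the hypoxia, p53 and myeloid lists, none of them called. B cell markers (median 0.23, adjusted p = 0.0951) and CD8 and NK markers (median 0.54, adjusted p = 0.0529) had positive medians without a call.

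Of the 9 lists called, cholesterol synthesis kept its call with an estimated correlation, and fry called the histones alone. The calls for glutamine, the unfolded protein response, ribosome biogenesis and T cell identity ended under TMM-style scaling (adjusted p = 0.0851, 0.0851, 0.0990 and 0.0898) and without KO activated 3 (adjusted p = 0.0931, 0.0988, 0.172 and 0.0931) or WT activated 2 (0.0815, 0.255, 0.304 and 0.201). Glutamine also lost its call without WT activated 3 (adjusted p = 0.0867), ribosome biogenesis without WT activated 1 (0.199), and the unfolded protein response without WT activated 1 (0.0517) or KO activated 2 (0.0561). The naive call ended without WT activated 3 (adjusted p = 0.0867) or KO activated 3 (0.0931). Thy1 ended without any of 8 libraries, WT activated 1 among them (adjusted p = 1.00). The power was limited: at these depths, limma found 4% of simulated 2-fold and 32% of 4-fold changes.

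**Figure D2:**
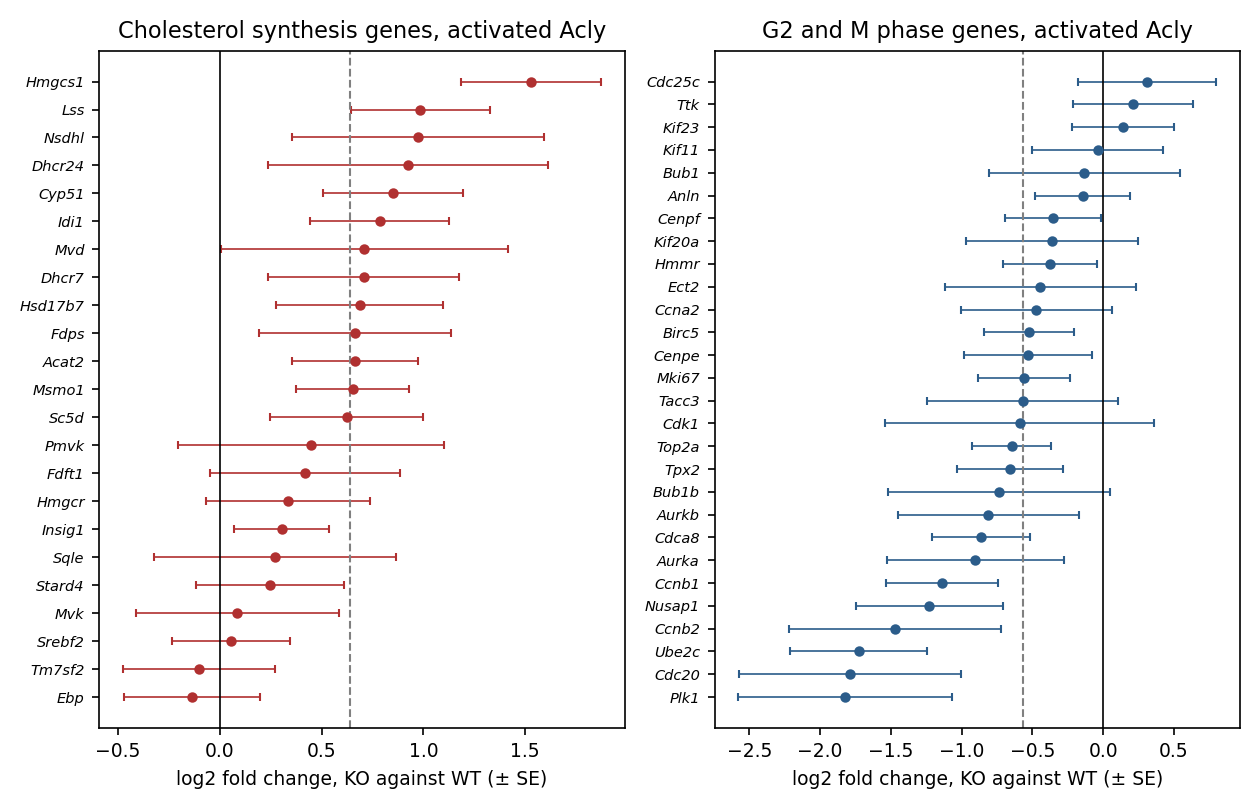
Log2 change of KO against WT in activated cells of the Acly cohort (horizontal axes) for genes of cholesterol synthesis (left, 23 of the 24 genes drawn) and of the G2 and M phases (right); bars are standard errors and dashed lines are medians of the whole lists. The medians were 0.64 and −0.56.

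Before stimulation the question is what the loss of Acly changes in resting cells. In resting Acly KO cells 3 lists were called, of which 2 were those of respiration. Nuclear genes of oxidative phosphorylation were lower (45 genes, 13 positive, median −0.19, camera adjusted p = 0.000229), as were genes of the mitochondrial genome (13 genes, 2 positive, median −0.32, adjusted p = 0.0130). Among them were the complex I subunits Ndufa10 (−1.07 ± 0.36) and Ndufb3 (−1.05 ± 0.36) and the complex IV subunit mt-Co3 (−0.59 ± 0.23), none past the threshold. Erythroid and platelet markers were higher (10 of 10 positive, median 0.67, adjusted p = 0.0189). All 3 calls were lost with an estimated correlation (adjusted p = 0.778 for each), and fry called none. In the means of these lists per library, all 3 KO libraries lay within the WT range for the mitochondrial genome (8.56 to 8.89 against 8.37 to 9.31), and 1 of 3 lay below every WT library for oxidative phosphorylation. Mitochondrial transcripts took 16395 and 13823 RPM in WT resting 1 and 2, 7687 RPM in WT resting 3 and 8580 to 10667 RPM in KO. The oxidative phosphorylation call ended without WT resting 1 (adjusted p = 0.0807) or WT resting 2 (0.345), and that of the mitochondrial genome without these (0.574 and 0.780) or KO resting 1 (0.354). The erythroid call ended without WT resting 1 (adjusted p = 0.0807), WT resting 3 (0.388) or KO resting 3 (0.592).

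limma called 0 of 31311 genes at rest (smallest adjusted p = 0.0626, 1745 at an unadjusted p under 0.05 with 841 higher and 904 lower, 1566 expected by chance), edgeR 1 (the model Gm5277) and DESeq2 0. This does not show that the genotypes are alike at rest, since limma found 4% of simulated 2-fold and 40% of 4-fold changes in this comparison. In the same simulated data it also called 17 genes that were not changed. In the real data the count of limma was 86 (54 higher, 32 lower) without trend and robust fitting, and 17 (6 and 11) with no filter. Adjusted over the list alone, 12 genes of 9 lists passed. The costimulatory receptor Tnfrsf4 (OX40) fell by 2.15 ± 0.43 (adjusted p = 0.000322) and the transcription factor Irf4 rose by 1.45 ± 0.32 (adjusted p = 0.000667). Fdft1, which makes squalene, fell by 2.00 ± 0.47 (adjusted p = 0.00261), and the glycolytic enzyme Tpi1 by 1.56 ± 0.41 (adjusted p = 0.00835). Left out, WT resting 3 raised the count of called genes to 119 and WT resting 1 raised it to 16.

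Activation of WT cells of the Acly cohort asks what 24 h of stimulation change by themselves. Transcripts of growth and division rose as a share of the library. The receptor for transferrin Tfrc rose by 5.47 ± 0.31 on the log2 scale, the transcription factors Irf4 and Irf8 by 6.06 ± 0.32 and 6.86 ± 0.34, and the ribonucleotide reductase subunit Rrm2 by 6.93 ± 0.28. Srm, which makes spermidine, rose by 8.80 ± 1.07 and the cold-shock protein gene Ybx3 by 8.02 ± 0.62. Granzyme B (Gzmb) rose at least 27.3-fold and interferon gamma (Ifng) at least 11.6-fold from resting groups with no count. Lad1 rose by 7.18 ± 0.49. The largest falls were those of Cd7 (at least 4.73-fold lower), Naip6 (at least 2.81-fold), the NK receptor Klrd1 (−3.84 ± 0.70), Rapgef4 (−3.63 ± 0.74) and Esp3 (at least 2.24-fold). limma called 14147 of 31311 genes, 6700 higher and 7447 lower, and each gene named here moved in the same direction in all 9 pairs of libraries. The split depends on the scaling: 47.4% of calls were higher here, while TMM-style scaling gave 7854 higher and 4499 lower and edgeR 8002 higher and 4607 lower. On the RPM scale the median change of all genes was −0.61 (−0.28 with TMM-style scaling), and −0.67 (−0.32) in KO cells. The larger background share of resting libraries, described above, lowers the RPM of cell transcripts there. How much of each rise this accounts for was not tested, in WT or in KO cells.

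On the RPM scale, metabolic lists rose together in activated WT cells, each called by camera. In oxidative phosphorylation all 45 nuclear genes rose (median 3.41, adjusted p = 8.70e-32), cytochrome c (Cycs) by 5.19 ± 0.23, and of 13 genes of the mitochondrial genome 9 rose (median 1.00, adjusted p = 0.000171, but 0.306 with an estimated correlation), mt-Nd1 by 2.08 ± 0.20. In glycolysis 16 of 19 rose (17 adjusted over the list alone; median 3.66, adjusted p = 8.09e-15), Pgam1 by 5.57 ± 0.24 and Gapdh by 4.40 ± 0.20. In the TCA cycle 16 of 17 rose (16, and 1 lower, adjusted over the list alone; median 2.71, adjusted p = 8.19e-12), with malate dehydrogenase Mdh2 at 3.79 ± 0.31. Acetyl-CoA supply had 9 higher and 2 lower of 19 (the same counts adjusted over the list alone; median 1.19, adjusted p = 0.00536). Pdha1 rose by 2.81 ± 0.31 and the citrate carrier Slc25a1 by 3.88 ± 0.43. In cholesterol synthesis 19 of 24 rose (median 2.33, 2.02 with genes at their bounds, adjusted p = 2.12e-08), Cyp51 by 4.13 ± 0.34 and Acat2 by 3.54 ± 0.31. Fatty acid synthesis had 12 of 17 higher (12, and 1 lower, adjusted over the list alone; median 1.81, or 1.63 at bounds, adjusted p = 8.34e-05, but 0.0926 with an estimated correlation), Fasn by 4.56 ± 0.54. Fatty acid oxidation had 9 higher and 2 lower of 17 (11 and 2 adjusted over the list alone; median 1.15, 0.73 at bounds, adjusted p = 0.0169, but 0.0518 with an estimated correlation). Glutamine and anaplerosis had 8 of 12 higher (8, and 1 lower, adjusted over the list alone; median 1.66, adjusted p = 6.64e-05), Got1 by 5.51 ± 0.30. The ATF4 targets had 12 higher and 5 lower of 23 (13 and 5 adjusted over the list alone; median 1.75, adjusted p = 0.000274), and one-carbon and nucleotide synthesis 19 higher and 1 lower of 23 (median 4.30, adjusted p = 3.13e-14). The serine synthesis enzyme Psat1 rose by 6.66 ± 0.28 and the nucleotide enzyme Umps by 6.13 ± 0.34. The list of LXR targets had 3 higher and 3 lower of 7 (3 and 4 adjusted over the list alone) and no camera call (adjusted p = 0.764).

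Lists of activation, division and biosynthesis rose in the same cells. T cell activation had 23 of 28 higher (median 3.32, adjusted p = 2.07e-15), and cytokines and effector molecules 14 higher and 1 lower of 22 (median 3.70, or 2.47 at bounds, adjusted p = 1.14e-07), the chemokine Ccl4 by 6.42 ± 0.46 and Tnf by 5.94 ± 0.57. In the S phase 29 of 30 rose (median 3.30, adjusted p = 2.24e-20), the replication clamp Pcna by 5.05 ± 0.25. In the G2 and M phases 18 rose and 3 fell of 28 (18 and 4 adjusted over the list alone; median 1.61, or 1.31 at bounds, adjusted p = 8.34e-05, but 0.0805 with an estimated correlation), Mki67 by 4.30 ± 0.32. Of 36 replication-dependent histones 26 rose and 1 fell (28 and 1 adjusted over the list alone; median 2.39, but 0.52 at bounds, adjusted p = 1.72e-08), Hist1h2ae at least 8.92-fold. Histone acetylation enzymes had 14 higher and 2 lower of 29 (median 1.10, adjusted p = 0.00108), the acetyltransferase Hat1 by 4.67 ± 0.32. In ribosome biogenesis 27 of 28 rose (median 4.42, or 4.38 at bounds, adjusted p = 2.25e-23), nucleolin (Ncl) by 4.44 ± 0.18. The unfolded protein response had 15 of 19 higher (16 adjusted over the list alone; median 2.87, adjusted p = 7.88e-10), the chaperone Hspa5 by 4.95 ± 0.29. All 15 T cell identity genes rose (median 1.96, adjusted p = 6.22e-11, but 0.0805 with an estimated correlation), Cd5 by 3.69 ± 0.31. Where no second count is given in these lists and in the metabolic ones, the count adjusted over the list alone was the same. On the RPM scale several called lists had a smaller median than T cell identity. They were acetyl-CoA supply, fatty acid synthesis, fatty acid oxidation, the mitochondrial genome, glutamine, ATF4 targets, the G2 and M phases and histone acetylation enzymes. For these lists a rise beyond that of T cell identity genes was not seen. T cell identity genes may themselves answer activation, so the comparison does not measure the part of the background.

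Other lists held rises and falls side by side, without a camera call. Naive and quiescence had 5 higher and 11 lower of 23 (6 and 11 adjusted over the list alone; adjusted p = 0.318): the receptors S1pr1 and Il7r fell by 3.25 ± 0.36 and 2.43 ± 0.31, and Slfn2 and Foxp1 rose by 2.68 ± 0.29 and 2.18 ± 0.25. Quantile normalization called this list lower (adjusted p = 0.00997). Inhibitory receptors had 4 higher and 2 lower of 13 (4 and 3 adjusted over the list alone; adjusted p = 0.262), with Cd200 and Pdcd1 (PD-1) up by 4.17 ± 0.33 and 4.94 ± 0.60. Regulatory T cell genes had 4 and 1 of 9 (adjusted p = 0.0976), helper lineage genes 4 and 6 of 19 (5 and 6 adjusted over the list alone; adjusted p = 0.691), with Tbx21 (T-bet) up by 5.94 ± 0.61. The interferon list had 8 and 10 of 31 (adjusted p = 0.372), with Gbp2 up by 6.32 ± 0.36, the p53 targets 5 and 2 of 19 (adjusted p = 0.257), and hypoxia 6 and 2 of 19 (adjusted p = 0.0976), with Nampt up by 4.0 ± 0.36. For the LXR, inhibitory, interferon and p53 lists the test pointed up while the median was negative. Markers of other cells were split as well. B cell markers had 3 higher and 7 lower of 17 (adjusted p = 0.318), Cd74 by 3.15 ± 0.66, myeloid markers 1 and 3 of 17 (1 and 1 adjusted over the list alone; adjusted p = 0.375), Cst3 by 2.82 ± 0.61, and CD8 and NK markers 1 and 6 of 13 (adjusted p = 0.145), Nkg7 by 4.14 ± 0.71. Erythroid markers had 0 and 1 of 10 (0 and 0 adjusted over the list alone; adjusted p = 0.653), stromal markers 0 and 5 of 9 (0 and 6 adjusted over the list alone; adjusted p = 0.0717), and sex-linked genes 0 and 2 of 6 (adjusted p = 0.371), Kdm5d by −1.41 ± 0.28. Nuclear RNAs had 4 and 4 of 11 (adjusted p = 0.371), with Snhg1 up by 3.50 ± 0.24 and Kcnq1ot1 down (−1.51 ± 0.15).

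Camera called 20 of the 35 lists in these cells, all higher. The other genes they were compared with include the background, which took a smaller share after activation. With an estimated correlation 15 kept the call, and fatty acid synthesis, the mitochondrial genome, fatty acid oxidation, the G2 and M phases and T cell identity did not. fry, which compares no list with other genes, called 32. Acetyl-CoA supply lost its call under a filter of 5 RPM (adjusted p = 0.0702).

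**Figure D3:**
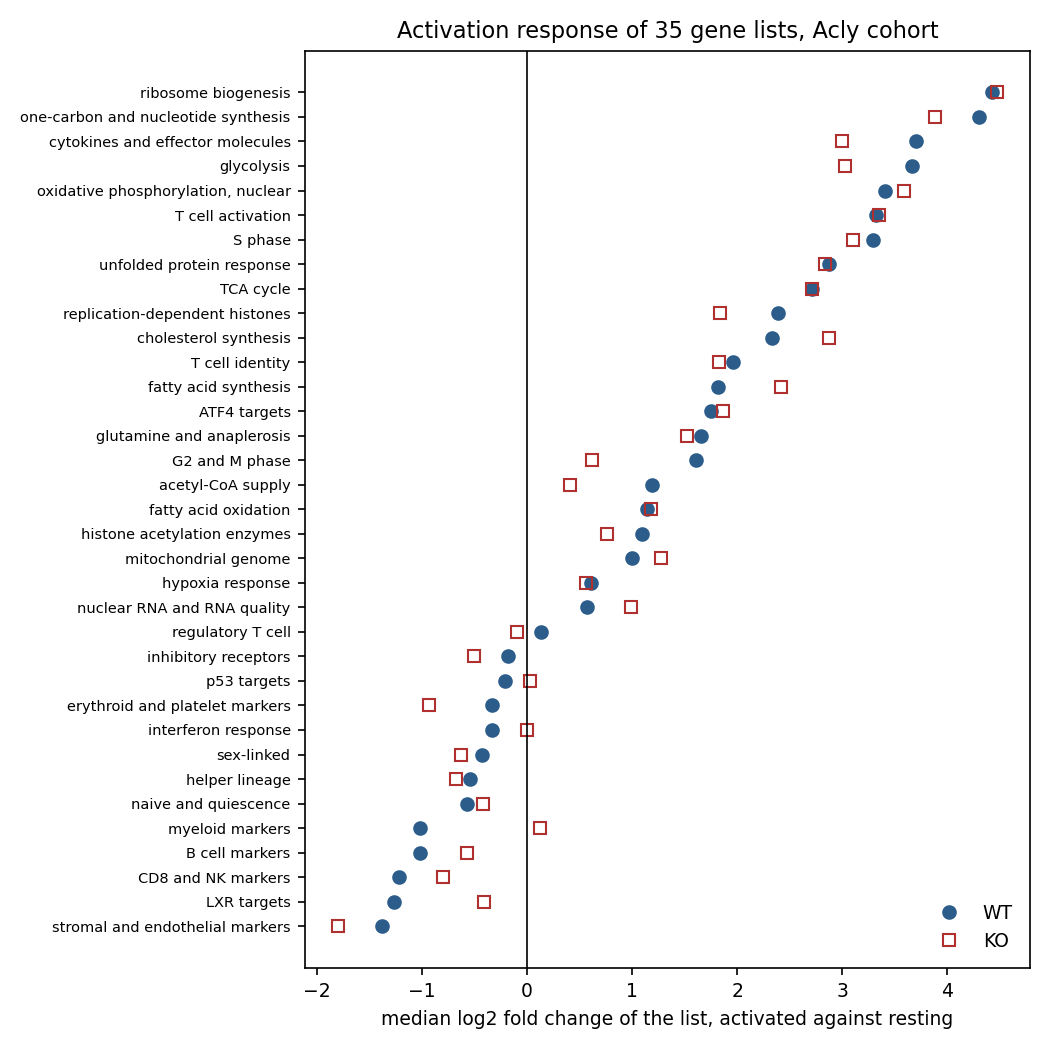
Median log2 change of activated against resting cells of the Acly cohort (horizontal axis) in each of 35 gene lists, for WT (filled circles) and KO cells (open squares). Nuclear genes of oxidative phosphorylation had medians of 3.41 and 3.59, and ribosome biogenesis had 4.42 and 4.47.

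Acly KO cells were compared in the same way to ask whether they activate. They raised the same kinds of genes: Ccl4 rose by 7.92 ± 0.46, Gbp2 by 7.34 ± 0.36, Tnfrsf4 by 7.19 ± 0.43, Irf8 by 6.47 ± 0.34 and Tfrc by 5.71 ± 0.31. Lad1 rose at least 37.7-fold and Nefh at least 23.2-fold. The largest falls were H2-Ob (−3.91 ± 0.68), Klrd1 (−3.70 ± 0.70), Mro (−3.70 ± 0.74) and the olfactory receptor genes Olfr1366 (−3.85 ± 0.78) and Olfr24 (−3.67 ± 0.60), which belong to the background described above. limma called 14846 genes, 6483 higher and 8363 lower (43.7% higher; 7842 and 4517 with TMM-style scaling), and DESeq2 called 9881 (6861 and 3020). Of the limma calls, 5692 higher and 5447 lower genes were also called in WT cells, where 1387 and 1989 would be shared by chance. Over 16250 genes the log2 changes of WT and KO cells had a Pearson r of 0.944, across genes, which are not independent replicates.

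In KO cells cholesterol synthesis had 20 of 24 genes higher (22, and 1 lower, adjusted over the list alone; median 2.87, or 2.52 at bounds, camera adjusted p = 5.73e-12), with Fdft1 at 5.57 ± 0.47 and Hmgcs1 at 3.57 ± 0.34. T cell activation had 23 of 28 higher (23, and 3 lower, adjusted over the list alone; median 3.35, adjusted p = 1.80e-14) and cytokines 16 of 22 (16, and 1 lower, adjusted over the list alone; median 2.99, or 2.52 at bounds, adjusted p = 3.87e-08). In the G2 and M phases 13 rose and 2 fell of 28 (median 0.62, or 0.34 at bounds, adjusted p = 0.00874, but adjusted p = 0.228 with an estimated correlation and adjusted p = 0.0784 under a filter of 5 RPM), Mki67 by 3.49 ± 0.32. Histones had 19 higher and 1 lower of 36 (21 and 1 adjusted over the list alone; median 1.84, or 0.86 at bounds, adjusted p = 1.78e-06). The naive list had 5 higher and 8 lower of 23 (6 and 8 adjusted over the list alone; adjusted p = 0.840), the homing receptor Ccr7 by 2.85 ± 0.32 and S1pr1 by −2.90 ± 0.36. Its median turned from −0.42 to 0.19 under TMM-style scaling. Stromal markers fell in 7 of 9 genes (8 adjusted over the list alone; adjusted p = 0.0202, and 0.202 with an estimated correlation). Camera called 21 lists, 20 of them higher, 15 with an estimated correlation, and fry called 29.

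The interaction asks whether the response to activation differs without Acly. Cholesterol synthesis rose more in KO than in WT cells (24 genes, 21 positive, median difference 0.76, camera adjusted p = 1.38e-06), and G2 and M phase genes rose less (28 genes, 8 positive, median −0.67, adjusted p = 0.000852). Neither call held with an estimated correlation (adjusted p = 0.144 and 0.527 with an estimated correlation). Adjusted over the list alone, Fdft1 (2.42 ± 0.66) and Hmgcs1 (1.68 ± 0.49) rose more (adjusted p = 0.0163 for both), as did Klf2 (1.80 ± 0.54) and Btg1 (1.35 ± 0.38) of the naive list (adjusted p = 0.0208 for both). Acly rose less, by −2.07 ± 0.62 (adjusted p = 0.0340). Irf4 (−1.73 ± 0.45, adjusted p = 0.0121) and the lactate carrier Slc16a1 (−2.55 ± 0.76, adjusted p = 0.0379) also rose less. Fdft1 was already lower and Irf4 already higher in KO than in WT cells at rest, as given above. Most of the interaction of these genes therefore came from their resting values. Over all genes limma called 0 of 31311 (1313 at an unadjusted p under 0.05, 527 higher and 786 lower; smallest adjusted p = 0.742), edgeR 6 and DESeq2 0. In the simulated data the interaction test found 0% of 2-fold and 20% of 4-fold changes.

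In the Pdha1 cohort 2 of 12 libraries correlated better with the other state of the cohort than with their own. The library labelled KO resting 3 had a median correlation of 0.898 with the activated and 0.631 with the resting libraries of the cohort, and the library labelled WT activated 3 had 0.675 and 0.907 (across 16250 genes). Against the means of the Acly cohort, KO activated 2 and 3 also lay nearer the resting (0.788 and 0.872) than the activated state (0.753 and 0.627). The early activation marker Cd69 stood at 118 RPM in KO resting 3 and at 5.06 to 13.2 RPM in the other 5 resting libraries. In activated WT libraries 1 to 3 it stood at 462, 159 and 17.2 RPM, and in KO at 104, 97.8 and 79.9 RPM. Ifng stood at 125 RPM in KO resting 3 and at 0 RPM in WT activated 3, below the floor of 3 counts. Both libraries were kept under their labels, so every contrast of this cohort mixes the states, and each is also given without these 2.

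**Figure D4:**
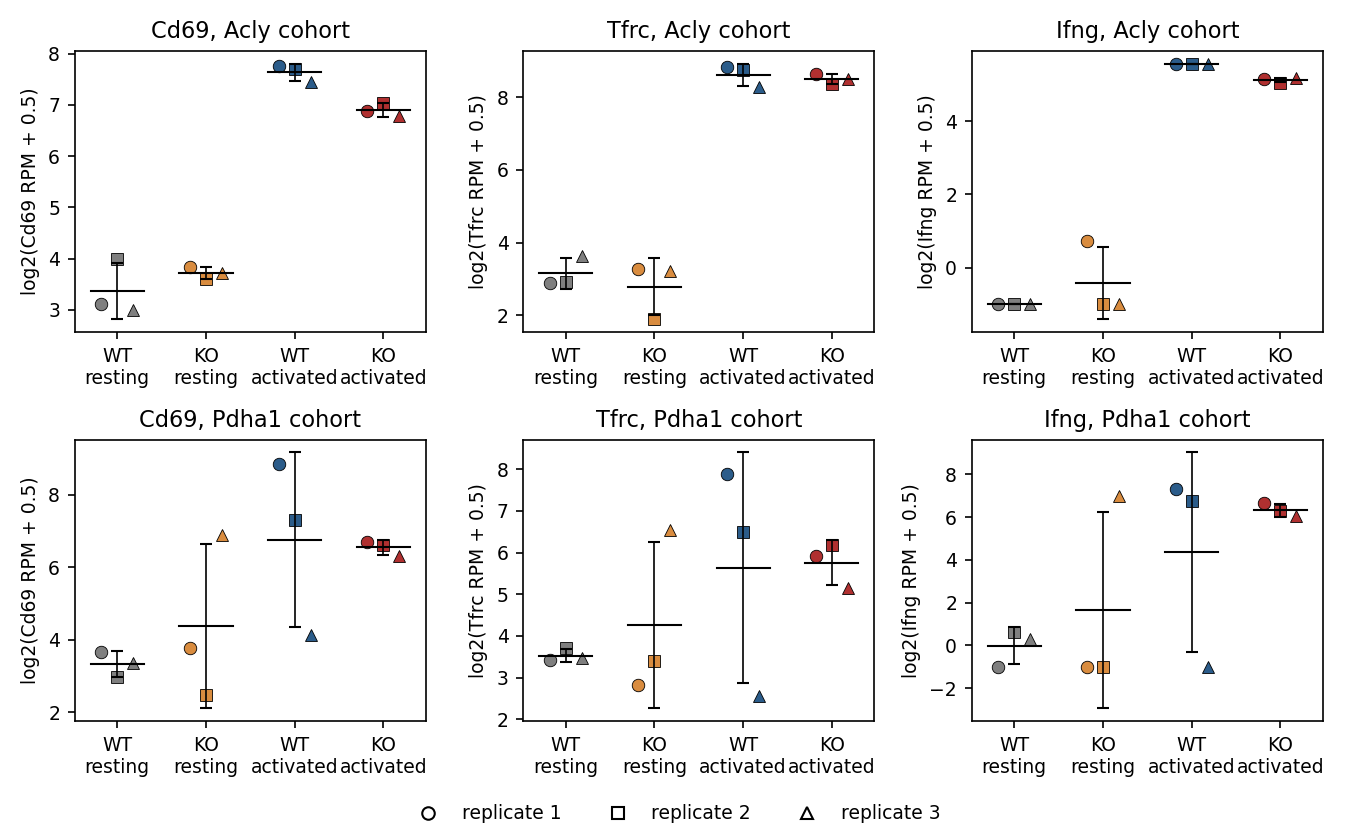
Cd69, Tfrc and Ifng as log2(RPM + 0.5) (vertical axes) by group in the Acly (top) and Pdha1 cohorts (bottom); the shape of a point gives the replicate number, lines are group means and bars are SD. The library labelled Pdha1 KO resting 3 had 118 RPM of Cd69 and the library labelled Pdha1 WT activated 3 had 17.2 RPM.

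As labelled, activation in the Pdha1 WT cells gave no gene past the threshold. limma called 0 of 30357 (4315 at an unadjusted p under 0.05, 2346 higher and 1969 lower; smallest adjusted p = 0.348), edgeR 0 and DESeq2 1922. Camera called 19 lists higher, among them T cell activation (26 of 28 positive, median 2.13, adjusted p = 1.18e-12), ribosome biogenesis (median 2.68, adjusted p = 7.83e-14) and oxidative phosphorylation (45 of 45 positive, median 2.42, adjusted p = 6.61e-21), each at adjusted p = 0.216 with an estimated correlation. Adjusted over the list alone, 12 genes rose, among them the T cell activation genes Batf (at least 6.92-fold) and Egr1 (4.18 ± 1.07) and the mitochondrial pyruvate carrier Mpc1 (4.38 ± 0.95). A single library decided this: without WT activated 3, 4338 genes were called, 2787 higher and 1551 lower. The 2 doubted libraries stand apart by their expression of activation genes, so activation results without them depend on a choice made from the values themselves, in WT and in KO cells. Without both, 7825 were called, 4315 higher and 3510 lower, with Ccl4 up by 8.32 ± 0.37, Gzmb by 8.04 ± 0.67 and Ifng by 7.07 ± 0.57. In that fit T cell activation genes rose in 23 of 28 cases (median 3.35, adjusted p = 5.32e-18, and 0.0480 with an estimated correlation). Its calls shared 3968 higher and 2365 lower genes with WT cells of the Acly cohort where 980 and 920 would be shared by chance.

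Activation of the Pdha1 KO cells also gave 0 calls as labelled (limma, 873 genes at an unadjusted p under 0.05; edgeR 0, DESeq2 1, Gm10863). Camera called 16 lists higher, T cell activation among them (27 of 28 positive, median 1.68, adjusted p = 5.53e-10, and 0.425 with an estimated correlation), with the early gene Nr4a1 at 3.48 ± 1.21. Without the 2 libraries 2075 genes were called, 2031 higher and 44 lower. Psat1 rose by 7.42 ± 0.92, Ifng by 7.33 ± 0.57 and Ccl4 by 6.61 ± 0.37. T cell activation genes rose in 16 of 28 cases (median 2.70, adjusted p = 8.87e-19, and 0.0431 with an estimated correlation), and 1955 of the higher genes were shared with Acly KO cells where 446 would be by chance. Of the lower genes 43 were tested in both cohorts and 13 were shared, with 13 expected by chance.

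For Pdha1 the question is what activated cells labelled KO express. A loss of its transcript was not seen with all libraries, while without WT activated 3 every KO library held less than the other WT libraries. As labelled, activated Pdha1 KO and WT cells did not differ in any gene by limma (0 of 30357; 856 at an unadjusted p under 0.05, 745 higher and 111 lower; smallest adjusted p = 0.380), with 0 calls by edgeR and 4 by DESeq2 (Fam129b and the models 9330159M07Rik, AC166164.1 and Gm10863). Camera called the S phase lower (30 genes, 11 positive, median −0.18, adjusted p = 0.0142, and 0.992 with an estimated correlation), with the licensing factor Cdc6 at −1.74 ± 0.80. That call ended under quantile normalization (adjusted p = 0.240), without WT activated 2 (0.0597) and without KO activated 3 (0.0632), and turned without WT activated 1 (adjusted p = 0.689). In the acetyl-CoA supply, fatty acid synthesis, glycolysis and ribosome lists the test pointed down while the median was positive. T cell activation genes had a median of 0.39 and no call (adjusted p = 0.980). Without the 2 libraries that list was called lower (3 of 28 positive, median −0.69, adjusted p = 1.06e-06, and 0.202 with an estimated correlation), as were oxidative phosphorylation (2 of 45 positive, median −1.10, adjusted p = 7.74e-16, and 0.231), one-carbon and nucleotide synthesis (median −0.98, adjusted p = 1.70e-07, and 0.200) and the S phase (median −0.81, adjusted p = 1.33e-07, and 0.200). In all, camera called 16 lists lower and 1 higher there, none with an estimated correlation. Single genes called in that fit were 2, the models Gm10863 and AC166164.1, and 32 higher and 510 lower by edgeR. The share of background moved with the genotype there, at 75403 to 89326 RPM of olfactory and vomeronasal receptors in KO against 26381 and 72243 RPM in WT activated 1 and 2. Leaving out WT activated 1 in its place, T cell activation was called higher (adjusted p = 0.000167).

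At rest, limma called 0 of 30357 genes between Pdha1 KO and WT (636 at an unadjusted p under 0.05, 397 higher and 239 lower), edgeR 0 and DESeq2 1 (the cytokine Il13). Camera called 12 lists higher and 2 lower, among them T cell activation (26 of 28 positive, median 0.90, adjusted p = 3.09e-06) and cytokines (23 of 25 positive, median 1.35, or 0.91 at bounds, adjusted p = 4.42e-06), each at adjusted p = 0.533 with an estimated correlation. They rested on the library labelled KO resting 3, without which the T cell activation list was at adjusted p = 0.994. Without the 2 libraries, T cell identity (2 of 15 positive, median −0.44, adjusted p = 0.000252) and erythroid markers (median −1.68, adjusted p = 2.08e-05) were lower, both at adjusted p = 0.998 with an estimated correlation, and Kcnmb4, a potassium channel subunit, was the only call (3.4 ± 0.49, limma, adjusted p = 0.0348), at 184 and 367 RPM in KO resting 1 and 2 and 17.7 to 36.7 RPM in WT. When only KO resting 2 was left out, the erythroid median turned to 0.38 (camera adjusted p = 0.560).

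The interaction in the Pdha1 cohort gave 0 calls (limma, 701 genes at an unadjusted p under 0.05; smallest adjusted p = 0.317; edgeR 0, DESeq2 4, namely Il13, Fam129b, Gm10863 and 9330159M07Rik) and 11 lists called lower, none with an estimated correlation (adjusted p = 0.813 with an estimated correlation for each). The strongest was oxidative phosphorylation (median −0.86, adjusted p = 1.91e-06), and glycolysis was lower too (median −1.0, adjusted p = 8.87e-05). All 11 calls ended without WT activated 1 (adjusted p = 0.710 and 0.375 for these 2) and all ended without KO resting 3 (0.836 and 0.375). In simulated data limma found 2.04% of 4-fold KO changes in activated Pdha1 cells as labelled.

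Whether activated cells labelled as Acly KO and as Pdha1 KO depart differently from their WT cells was tested in all 24 libraries. The deletion of Pdha1 was neither shown nor excluded, as given above. Its activated WT group also holds WT activated 3, which resembled resting libraries. The Pdha1 effect below is therefore only the difference between groups as labelled. The Acly effect exceeded the Pdha1 effect in cholesterol synthesis (median difference 0.24, camera adjusted p = 0.0138), and lay below it in the G2 and M phases (median −0.65, adjusted p = 0.0138) and histones (median −0.98, adjusted p = 0.0138). These were at adjusted p = 0.814, 0.576 and 0.246 with an estimated correlation. Klf2 differed by 2.75 ± 0.65 (list-adjusted p = 0.00315), while Hmgcs1 (1.00 ± 0.61), Nusap1 (−2.82 ± 1.01) and Hist1h3h (−2.79 ± 0.92) did not pass. limma called 0 of 35290 genes (1141 at an unadjusted p under 0.05, 204 higher and 937 lower; smallest adjusted p = 0.605), edgeR 0 and DESeq2 2 (Fam129b and 9330159M07Rik). The cholesterol difference rested on single libraries: without Pdha1 WT activated 1 its median was −0.01 (adjusted p = 0.638), and the call also ended without Pdha1 WT activated 2 (0.0587), Pdha1 KO activated 3 (0.0692), Acly WT activated 3 (0.0712) or Acly KO activated 1 (0.0641). The histone difference ended under a filter of 5 RPM (adjusted p = 0.434), under quantile normalization (0.102) and without the 2 doubted libraries (0.116), as well as without Pdha1 WT activated 3 (0.108), Pdha1 WT activated 2 (0.0587), Acly WT activated 1 (0.0537) or Acly KO activated 3 (0.0759). The G2 and M phase difference ended without Acly WT activated 2 (adjusted p = 0.0908). Across 16244 genes, which are not independent replicates, the effects of the 2 deletions had a Pearson r of 0.0221 in activated cells (Spearman 0.0437) and −0.114 at rest (Spearman −0.132), and 0.0718 and 0.0352 without the 2 libraries. The activation responses of the cohorts had r of 0.861 in WT and 0.754 in KO cells.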

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

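The list tests of the interactions and of the difference between the deletions were fixed beforehand, while the tests of explanations below and the counts of splits were chosen after the results were seen. In activated cells the Pdha1 effect named below is that of the groups as labelled, and its WT group mixes the states.

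Cholesterol synthesis genes stood out because they answered activation more strongly in Acly KO than in WT cells (camera adjusted p = 1.38e-06, median difference 0.76, and 0.144 with an estimated correlation), and because the Acly effect in activated cells exceeded the Pdha1 effect (adjusted p = 0.0138, median 0.24, but 0.814 with an estimated correlation, and a median of −0.01 with adjusted p = 0.638 without Pdha1 WT activated 1). The tables argue against library scaling, since the median KO effect in activated cells stayed at 0.64 or more under TMM-style scaling and quantile normalization. They argue against unequal sex of the mice too, since the median was 0.66 with an Xist covariate. The background covariate cannot decide, because receptor genes took like shares in activated KO (31451 to 40962 RPM) and WT libraries (30101 to 40314 RPM). A set of 11 repeat gene models took 94176 to 148627 RPM in KO and 63917 to 97447 RPM in WT. No fit adjusted for them, so background of that kind stays open. Weaker activation of the KO cells is argued against by direction only: it would lower a list that rises with activation, and this list was higher. The list lay 0.65 above the change predicted from the activation response of the Pdha1 WT cells without the 2 doubted libraries, in which it rose (median 1.24 over its 22 genes in that regression). The regression was almost flat (slope −0.022, Pearson r −0.0907) and predicted only −0.11, so that distance largely restates the KO effect. Its standard error of 0.0844 is over genes, which are not independent replicates, and does not measure the spread between samples. A response of SREBP2, the factor that raises sterol synthesis when sterols run short, is a candidate explanation that stays open. Its 3 tested targets outside the enzymes all had positive changes, with a median of 0.26 and a mean of 0.27. The standard error of that mean was 0.18, with the genes taken as independent. The median lay under the limit of 2 such standard errors, a limit made stricter after the value was seen. The 10 splits of the 6 activated libraries are too few for a share under 0.05, with a median of 0.64 in the real split and 0.27 in the highest of the others.

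Genes of the G2 and M phases stood out because they rose less with activation in Acly KO than in WT cells (adjusted p = 0.000852, median −0.67, and 0.527 with an estimated correlation) and because the Acly effect lay below the Pdha1 effect (adjusted p = 0.0138, median −0.65, and 0.576 with an estimated correlation), as it did for replication-dependent histones (adjusted p = 0.0138, median −0.98, and 0.246). Library scaling is argued against, since the medians nearest 0 in activated cells were −0.39 and −0.72 under TMM-style scaling, quantile normalization and the background covariate. Unequal sex of the mice is argued against too, with −0.61 and −0.76 under an Xist covariate. Background stays open for these lists as well, because the receptor shares of the genotypes were alike and the repeat gene models were not adjusted for. Weaker activation of the KO cells stays open for both lists. The G2 and M phases lay at −0.45 (standard error over genes 0.110) and the histones at −0.49 (0.568, over only 2 genes) beyond the change predicted from the activation response of the Pdha1 WT cells, but neither list rose in those cells (medians −0.45 and −0.76), so the prediction would lie near 0 whatever the cause. This condition was added after the values were seen. The 10 splits are too few for a share under 0.05, with absolute medians of 0.56 and 0.82 in the real split and 0.37 and 0.46 in the highest of the others.

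As labelled, 11 lists of the Pdha1 cohort answered activation less in KO than in WT cells. Within the cohort exactly 2 libraries, labelled KO resting 3 and WT activated 3, correlated better with the other state than with their own. Against the means of the Acly cohort, KO activated 2 and 3 also lay nearer the resting (0.788 and 0.872) than the activated state (0.753 and 0.627). An exchange of the labels of KO resting 3 and WT activated 3 stays a candidate explanation of where those libraries sit, as each stands in the place the other should take. Whether it bears on the interaction stays open. Without both libraries 13 lists were called lower, with oxidative phosphorylation at a median of −0.94 (adjusted p = 2.06e-09, but 0.360 with an estimated correlation and 0.638 with fry) and glycolysis at −1.04 (9.42e-06, but 0.289 and 0.312). As labelled, all 11 calls ended without WT activated 1 and also without KO resting 3. Low depth is argued against, since 3 libraries of the cohort with fewer counts than either sat with their own state. Stimulation that failed in a culture and happened in another stays open, because the library labelled WT activated 3 correlated better with WT than with KO resting libraries by only 0.027, within the widest spread of 0.0783 between them. No biological explanation was tested, and the Pdha1 transcript as labelled does not tell the genotypes apart. Without WT activated 3 it was lower in every activated KO library, as was the transcript of Acly, so that order does not settle the genotype.

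The lists of that interaction were glycolysis (camera adjusted p = 8.87e-05, median −1.0), the TCA cycle (0.000279, −0.77), nuclear genes of oxidative phosphorylation (1.91e-06, −0.86) and one-carbon and nucleotide synthesis (0.00134, −0.64). They also held T cell activation (0.00300, −0.64), cytokines and effector molecules (0.00357, −0.95), the S phase (8.87e-05, −0.69) and histone acetylation enzymes (0.0322, −0.36). The unfolded protein response (0.00134, −0.75), the hypoxia response (0.0206, −0.68) and ribosome biogenesis (0.00131, −0.65) complete the 11, all at 0.813 with an estimated correlation. None of the 13 lists called without the 2 doubted libraries kept its call with an estimated correlation (smallest adjusted p = 0.289). Between the deletions, naive and quiescence genes (adjusted p = 0.0182, median 0.05) and erythroid and platelet markers (adjusted p = 0.0177, median 1.16) had a higher Acly than Pdha1 effect, both at 0.814 with an estimated correlation. The naive call ended without Acly KO activated 3 (adjusted p = 0.0759), where its median turned to −0.05 as it also did without Pdha1 WT activated 2 (−0.13) and Pdha1 KO activated 2 (−0.01), and the erythroid call without Pdha1 WT activated 1 (0.257), among others.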

How the results depend on the processing

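Of the alternatives, edgeR, DESeq2, the background and Xist covariates and the fits without 2 or 3 doubted Pdha1 libraries were chosen after the results were seen, as were the genes named for small counts. Most results kept their direction and their side of the threshold, a tally that includes results never called. Counts of calls stayed within 1.5 times of those reported in 230 cases and moved in 74, and among named genes 6379 values kept both while 156 passed and 16 lost the threshold, and 53 that passed in neither changed sign. List tests kept both in 6671 cases, and 281 calls were lost, 199 gained, 42 turned and 402 tests called in neither changed direction. Most contrasts reported 0 calls, and a count of 0 that stayed 0 is among the cases kept. Most list tests were likewise not called as reported, and a test that stayed uncalled in the same direction is among those kept. These tallies therefore do not measure how robust the calls are. Of the list calls that compare genotypes or deletions, only cholesterol synthesis in activated Acly KO cells held with an estimated correlation. Acly in activated KO cells ranged from −3.24 to −2.62 and passed in 25 of 26 alternatives (not in limma without trend and robust, adjusted p = 0.426). Thy1 ranged from −1.42 to −1.16 and passed in 12 of 26. Depth limits what can be seen near the floor, where a count of 0 allows up to 2.03 to 6.83 RPM per library. In data simulated at the depths and spreads of these libraries, limma found 4% of simulated 2-fold and 32% of 4-fold KO changes in activated Acly cells, 0% and 2.04% in activated Pdha1 cells, and 0% and 20% in the Acly interaction. A 1.6-fold shift of the cholesterol list was found in the Acly cohort (adjusted p = 3.72e-14, and 0.00711 with an estimated correlation) and in the Pdha1 cohort only with the preset correlation (0.00237, and 0.0781). The simulated genes were drawn without correlation between them, so the power for lists of correlated genes was not measured. For every value below that departs from the reported count, the cause was not tested.

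In Acly KO against WT cells at rest (0 reported), the calls were 4 with a pseudocount of 0.1 (Gm5292, Nefh, Ramp2 and Tmem160), 17 with no filter (6 higher, 11 lower), 1 with only the groups compared (Gm5277), 86 with limma without trend and robust (54 higher, 32 lower) and 1 with edgeR (Gm5277). After activation (2 reported) they were 1, Acly, with a pseudocount of 0.1, a filter of 5 RPM, TMM-style scaling, quantile normalization or the Xist covariate, 0 with limma without trend and robust, 8 with no filter (3 higher, 5 lower), 39 with only the groups compared (4 higher, 35 lower), 16 with edgeR and 4 with DESeq2. The Acly interaction (0 reported) gave 4 with no filter (Arhgap26, Gcsh, Gm44432 and Igsf8) and 6 with edgeR (2 higher, 4 lower). Activation of Acly KO cells gave 14846 calls in limma and 9881 in DESeq2.

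limma called 0 in each contrast of the Pdha1 cohort as labelled. There, no filter gave 2 calls in activated KO against WT cells and 2 in the interaction (Fam129b and Gm10863 in both). DESeq2 gave 1 at rest (Il13), 4 after activation, 1922 for activation of WT (1900 higher, 22 lower), 1 for activation of KO (Gm10863) and 4 for the interaction. In this order, fits without the 2 doubted libraries gave 1 (Kcnmb4), 2 (AC166164.1 and Gm10863), 7825, 2075 and 2 (Fam129b and Gm10863), and edgeR without them gave 5 (Gata6, Gpatch2, Kcnmb4, Lyrm7 and Zcchc3), 542, 5768, 3180 and 9. Fits without the 3 gave 5 (Gata6, Kcnmb4, Lyrm7, mt-Nd4l and Zcchc3), 0, 2486, 2991 and 0, and edgeR without them gave 6, 2 (AC166164.1 and Ldhb), 3799, 3350 and 2 (9330159M07Rik and AC166164.1). The difference between the deletions (0 reported) gave 1 with only the groups compared (Trmt112-ps1), 2 with DESeq2 (Fam129b and 9330159M07Rik), and 300 and 9 with edgeR without the 2 and the 3 libraries.

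Leaving out each library in turn (the remaining 2 libraries of a group are assumed to vary like the others) gave 0 to 119 calls in resting and 1 to 4 in activated Acly KO against WT cells, 11095 to 14150 for activation of WT, 12299 to 15512 for activation of KO and 0 to 1 for the interaction. For Pdha1 it gave 0 at rest, after activation and for activation of KO, 0 to 4338 for activation of WT, 0 to 1 for the interaction, and 0 to 1 for the difference. List tests turned in the same cohort. For cytokines at rest the adjusted p ran from 9.34e-09 to 0.994, turning without KO resting 3 (0.994). For the S phase in activated KO against WT cells it ran from 5.17e-07 to 0.689, turning without WT activated 1 (0.689). For T cell activation genes in the same contrast it ran from 6.23e-05 to 0.999, turning without WT activated 3 (6.23e-05), and fits without the 2 (1.06e-06) and the 3 libraries (0.00411) turned it too.

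Replicate numbers do not pair the libraries by the labels. Deviations from group means of resting and activated libraries with the same genotype and number correlated at 0.0536 to 0.231 in the Acly cohort, where each resting library matched its own number best, and at −0.518 to 0.0583 in the Pdha1 cohort, where 1 of 6 did. KO and WT libraries of the same number and state correlated at 0.0361 to 0.187 in the Acly cohort, at −0.0023, 0.409 and 0.433 in resting and at 0.361, 0.117 and 0.509 in activated Pdha1 cells. The match of resting with activated libraries in the Acly cohort is a hint that a genotype and number may mark a shared source. In both cohorts most KO libraries matched the WT library of their own number best, a hint that a number may be shared across genotypes. In the Pdha1 cohort the values 0.433 and 0.509 each involve a doubted library. Those 2 libraries also shift the group means, so the mix of states cannot be told apart from a shared number there. The tests of KO against WT as reported ignore a shared number. Those of activation and of the interaction ignore a shared genotype and number. The block gave 0 calls in every Pdha1 contrast, and in activated Pdha1 KO cells it called erythroid and platelet markers lower (adjusted p = 0.0217, against 0.0696). With the replicate number as a block the calls were 2 in resting Acly KO cells (Cluh and Tmem160), 5 in activated ones (Acly, Thy1, Bri3bp, Arhgap26 and 6330419E04Rik), 1 in the Acly interaction (Arhgap26) and 6 in the difference between the deletions. A block by genotype and number gave 3 in the Acly interaction (6330419E04Rik, Arhgap26 and Gm44432).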

Other observations

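The counts of splits and the genes named in this part were chosen after the results were seen.

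edgeR, run on the recovered counts, called genes in activated Acly KO cells that limma did not call. Rgs2, a regulator of G protein signalling, was higher by 1.6 on the log2 scale (adjusted p = 0.00119), as were the coactivator Ncoa2 by 1.20, the T-box factor Eomes by 1.42 and Cd74, the invariant chain of MHC class II, by 1.25. Taf1, a subunit of the general transcription factor TFIID, was lower (−1.56), as were Igsf8 (−1.55), Bri3bp (−1.29) and the copper transporter Atp7b (−5.49). Cd74 stood at 24.0, 16.6 and 10.6 RPM in activated WT and at 41.0, 43.4 and 26.8 RPM in activated KO libraries 1 to 3. Among cytokines that did not pass in limma, Il9 stood at 2.16 ± 0.78 and Il21 at −2.23 ± 0.84, while interleukin 2 (Il2) stood at 53.2, 34.1 and 20.3 RPM in WT and at 26.5, 19.4 and 24.6 RPM in KO.

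The cohorts differed in transcripts of other blood cells. The globin gene Hbb-bs ranged from 3.95 to 198 RPM in the Acly cohort and from 280 to 7161 RPM in the Pdha1 cohort, and the kappa light chain Igkc from 0 to 18.3 RPM and from 15.2 to 313 RPM.

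Resting Acly libraries split in a way that did not follow genotype. The real split of the 6 resting libraries gave 0 calls, and the highest of the other splits gave 157, by setting WT 1, WT 2 and KO 1 against WT 3, KO 2 and KO 3. That points to a structure of the samples. Xist stood at 9.28, 15.5 and 10.3 RPM in the first set and at 40.3, 42.8 and 55.7 RPM in the second, so the sex of the mice is a candidate source of this split, and no separate test of it was made. With 10 splits no share under 0.05 can be reached. In activated Acly cells the real split gave 2 calls, the highest other also 2, and 2 of the 10 splits gave as many.

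For activation in the Acly cohort the real splits gave 14147 calls in WT and 14846 in KO and every other split gave 0, and 10 splits are again too few. In the Pdha1 cohort the 4 contrasts gave 0 calls in the real and in every other split. Of 100 drawn splits for each interaction and for the difference between the deletions, the highest counts were 13 for the Acly interaction, 4 for the Pdha1 interaction and 1 for the difference. The real count was 0 in each, which all 100 splits reach by construction, so these counts say nothing about chance.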
